A study of Mus musculus with 4 samples.

How the data were processed

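Nuclei from the middle slice of mouse kidneys were profiled by droplet single-nucleus RNA sequencing in 4 libraries, 2 control and 2 from Hoxb7-Cre; Grhl2 fl/fl mice, with 1 library of each genotype per kit version (v2 and v3.1), per the labels. The deposited files hold unfiltered UMI counts for 31053 genes and every listed barcode, which the authors made with Cell Ranger 3.0.2, per the file headers and the submitters' processing notes. These notes also name Seurat 2.3.1, without its role. The genome build, the annotation and whether intronic reads were counted are not given in the sources used here. The integer values and the barcode numbers (737280 for v2, 6794880 for v3.1) were checked on the files. Uty and the other Y-linked genes were detected in all libraries, and Xist lay between 0.27 and 1.39 CPM.

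A barcode was called a nucleus at 500 UMIs or more and at 10% or more of the 99th percentile of the 5000 largest barcodes, which gave thresholds of 500, 500, 715.9 and 531.3 UMIs (control replicate 1, knockout replicate 1, control replicate 2, knockout replicate 2, an order kept below). At least 200 genes and at most 5% mitochondrial UMIs were required. This called 12594, 15656, 9604 and 12657 nuclei. Nuclei were scored against simulated doublets (Scrublet in scanpy) and the highest scores removed at an expected rate of 0.8% per 1000 nuclei (1269, 1961, 738 and 1282). Counts were scaled and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0 with seed 1 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9). Principal cell and urothelium clusters were clustered again at resolution 0.1 with 1000 variable genes and 15 components, which left 30 clusters. Clusters were named from markers of 14 classes fixed beforehand, where at least 3 markers lay more than 1 log2 above the mean of the other clusters (pseudocount 20 CPM) and no other class had more markers among the 10 leading genes. Clusters that scored highest for principal cells, with 3 markers raised and a higher sum of the medullary than of the cortical collecting duct list, formed the inner medullary clusters whatever their leading genes. 1 of the 2 would have had no name by the rule on leading genes. Clusters with a correlation of 0.95 or more to the profile of empty droplets were left out (2489, 3496, 20 and 368 nuclei). Other clusters without a name held 3.02%, 3.77%, 1.12% and 1.97% of the nuclei used. The nuclei used held 21.9%, 23.8%, 42.5% and 45.1% of each library's UMIs.

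The share of free RNA in a class was estimated from transcripts of another cell type and from barcodes with 1 to 50 UMIs. It was 61.8%, 61.2%, 31.7% and 31.0% of the UMIs in principal cells, 40.4%, 42.6%, 21.8% and 23.3% in the proximal tubule and 80.9%, 75.9%, 44.1% and 54.7% in immune nuclei. Subtraction left too few UMIs to test 36 of the 202 genes called in principal cells, 22 of 68 in intercalated cells, 19 of 50 in the connecting tubule, 5 of 10 in the distal convoluted tubule, 15 of 51 in the thick ascending limb, 2 of 20 in the thin limb, 2 of 18 in the proximal tubule, 8 of 14 in endothelial nuclei, 2 of 3 in podocytes and 17 of 138 in the inner medullary clusters. Genes that made up more than 0.1% of the free RNA are said to be abundant in it. A gene said to have less than 50% of its UMIs left in a class had so with both profiles of free RNA.

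UMIs were summed per library and class. The classes set beforehand for a comparison and the inner medullary clusters were tested where each library had at least 20 nuclei. Stromal nuclei were too few. Urothelium, macula densa and parietal epithelium were not among the classes set for a comparison, and their genes were not tested. Genes were filtered by edgeR's count filter, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), with a term for the kit, which pairs the libraries and leaves 1 residual degree of freedom. P-values were adjusted by Benjamini-Hochberg within each class at a threshold of 0.05. DESeq2 1.42.0 was run on the same sums. The difference between principal cells and the thick ascending limb was tested as an interaction, with a block for each library and a kit term within the class. 30 fixed gene lists were tested by camera (limma 3.58.1, correlation 0.01) where at least 3 members were measured, adjusted over all 266 pairs of list and class. They were tested again with a correlation estimated from the data and by fry, which asks whether the genes move one way on balance, and whose mixed form asks whether they move in either direction. In the inner medullary clusters the osmotic stress list was tested without the leading genes of the clusters and without the 2 collecting duct lists, and adjusted in place of the full list among the 266 pairs. Shares of nuclei were compared by exact permutation. Intervals are exact 95% intervals. A fold against a group at 0 used a floor of 3 counts over the group.

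Genes were named by rule. For principal cells these were Grhl2, the 10 higher and 10 lower genes with the smallest p that passed 0.05 with the same sign in both library pairs, and members of the lists. For other classes 5 per direction were taken, and 5 per direction for the interaction. Of the list members, up to 4 per list in principal cells and up to 3 in other classes were eligible, and those printed are examples. For genes printed as past the threshold, values that changed sign or fell under 50% of their size with 1 library left out are given. Some genes that the rule selects are not reported here.

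The groups, the comparisons, the tests, the markers, the lists and most alternatives were set before the data were examined. The second clustering and its resolution (6 were looked at), the naming thresholds, the second profile of free RNA (100 to 300 UMIs), the inner medullary class and its shortened list, equal nuclei without the immune class, clustering without the genes called in the collecting duct, the control nuclei split into 2, 3 and 4 parts, the UMIs left per called gene and class, and leaving out libraries for the interaction and the shares were chosen after. The alternatives set beforehand were another scaling (RLE), DESeq2, no count filter, no kit term, UMI minimums of 500 and 1000, mitochondrial limits of 1% and 10% (for the number of nuclei called alone, with no class or share repeated), doublets kept, Leiden resolutions of 0.5 and 1.5, free RNA subtracted, equal numbers of nuclei (24 per library and class, 94 without immune nuclei, seed 7), and each library left out.

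The tests were tested on simulated data with 200 genes changed. Counts were drawn from the mean of both genotypes per kit and the dispersion trend fitted to each class of these libraries. This meets the assumptions of edgeR, so the rates below do not measure false calls in the real data. In principal cells edgeR called 51.1% of 92 genes changed by a log2 of 1 and 94% of 83 changed by 2, 3.1% of its calls were unchanged genes, and it called 0 genes when none was changed. DESeq2 called 4.3% and 57.8% of the same genes. The interaction test called 25% of 100 and 75.8% of 99.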

Results

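Single-nucleus RNA sequencing of a slice through the middle of the mouse kidney was deposited for 4 libraries. 2 came from control mice and 2 from mice in which Hoxb7-Cre, a recombinase active in the collecting duct lineage, was combined with floxed Grhl2. Grhl2 encodes a transcription factor that sets junction and barrier genes in epithelia. Each genotype had 1 library made with the v2 kit (replicate 1) and 1 with the v3.1 kit (replicate 2), so that each kit gave 1 pair of libraries. The libraries held 31036399 UMIs (control replicate 1), 36166604 (Grhl2 knockout replicate 1), 47751043 (control replicate 2) and 41084519 (Grhl2 knockout replicate 2). After calling nuclei and setting aside clusters that resembled empty droplets, 8836, 10199, 8846 and 11007 nuclei were used, in the same order, with a median of 726, 785, 2081 and 1526 UMIs each. Classes are named for the nuclei that carry the markers of that cell type, and a class name stands for nuclei like that type. The description of the series speaks of a single knockout and a single control littermate, while 4 libraries are deposited. Nothing therefore shows that the libraries of a genotype came from separate animals, and p-values concern only these libraries. With 1 residual degree of freedom, edgeR draws most of the spread it uses for a gene from the trend over all genes. A small p is thus no measure of how far that gene varied between libraries of a genotype. Intervals cover counting error only.

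Grhl2 was detected in principal cell nuclei of every library. It reached 102 CPM in control replicate 1 (exact Poisson 95% interval 61.5 to 159.6, 19 UMIs), 90.8 in knockout replicate 1 (53.8 to 143.5, 18 UMIs), 195 in control replicate 2 (153.0 to 244.6, 74 UMIs) and 298.5 in knockout replicate 2 (241.5 to 364.8, 95 UMIs). Its log2 change was 0.43 (SE 0.28, n = 2 per group, edgeR adjusted p = 0.54), and without knockout replicate 2 it was -0.65. In the inner medullary clusters described below it was higher in the knockout of both kits, at 31.7 and 70.5 CPM (v2) and 181.9 and 371.5 (v3.1), with a log2 change of 1.22 (SE 0.38, edgeR adjusted p = 0.118). With these clusters counted as principal cells it was at 54.9 and 84.7, and 186.7 and 323.6, and passed the threshold as higher (log2 change 0.83, edgeR adjusted p = 0.0369). The UMIs are 3′ tags and the labels do not say which part of the gene was deleted, so these values do not check the labels, and the knockout libraries are the libraries labelled knockout throughout. In nuclei of the proximal tubule, which lies outside the Hoxb7 lineage, Grhl2 lay between 0.9 and 2.2 CPM.

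The first comparison asked which genes differ in the principal cells of the collecting duct, the cells that reabsorb water and sodium. The raised genes with the smallest p, taken by rule, were as follows. Nlgn1, a neuroligin of cell adhesion, had 0 UMIs in the control libraries and 240 in the knockout libraries, at least 87.6-fold higher against a floor of 3 counts over the group. Ctnnd2, a delta-catenin, had 1 and 175 UMIs, a ratio of 192 (counting interval 34.0 to 7610). Pde10a, a cyclic nucleotide phosphodiesterase, rose from 135 ± 78.6 to 1137 ± 77.5 CPM (SD, n = 2), a log2 change of 3.02 ± 0.24 (SE). Kcnip4, a subunit that modulates voltage-gated potassium channels, rose by a log2 of 3.59 ± 0.39, and Kcnh7, a potassium channel, by 3.04 ± 0.44. The other raised genes named by the rule were Samd5 (2.75 ± 0.37), Thsd7a (2.52 ± 0.39), Spp1 (1.67 ± 0.20) and the matrix proteases Adamts1 and Mmp16. Adamts1 had 3 UMIs in the control and 54 in the knockout libraries (ratio 19.7, 6.40 to 98.6) and Mmp16 had 2 and 47 (ratio 25.7, 6.74 to 219). Spp1, which encodes osteopontin, was abundant among the free RNA of the droplets.

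Among the genes that fell, Sox5, an SRY-box transcription factor, went from 578.5 ± 335 to 67.4 ± 35.4 CPM (log2 change -3.10 ± 0.29 SE, n = 2 per group). Fras1, a basement membrane protein, changed by -2.30 ± 0.26, Il17re, a receptor of the interleukin 17 family, by -3.88 ± 0.53, and Thsd4, a matrix protein, by -2.57 ± 0.37. Ralyl changed by -1.95 ± 0.27, Chst9, a sulfotransferase, by -1.84 ± 0.27, and Mpped2 by -1.56 ± 0.23. Myo3b, a class III myosin, had 46 UMIs in the control and 0 in the knockout libraries, at least 14.0-fold lower. Atp10b, a phospholipid flippase, had 75 and 2 UMIs (knockout over control 0.0292, 0.00347 to 0.109) and Macc1 had 48 and 1 (0.0228, 0.000566 to 0.133). All of these genes moved the same way in both library pairs, as the rule for naming them required. With 1 library left out, Samd5 was at 1.13 and Thsd7a at 1.01 (knockout replicate 2) and Thsd4 at -0.81 (control replicate 2). Leaving out a library also drops the kit term and compares genotypes across kits, here and below, so these values do not measure the weight of that library alone. In the v2 pair, which is left whole in these cases, the log2 differences were 1.99, 2.79 and -2.26. Their edgeR adjusted p-values lay between 1.84e-43 (Nlgn1) and 1.84e-08 (Thsd7a).

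**Figure D1:**
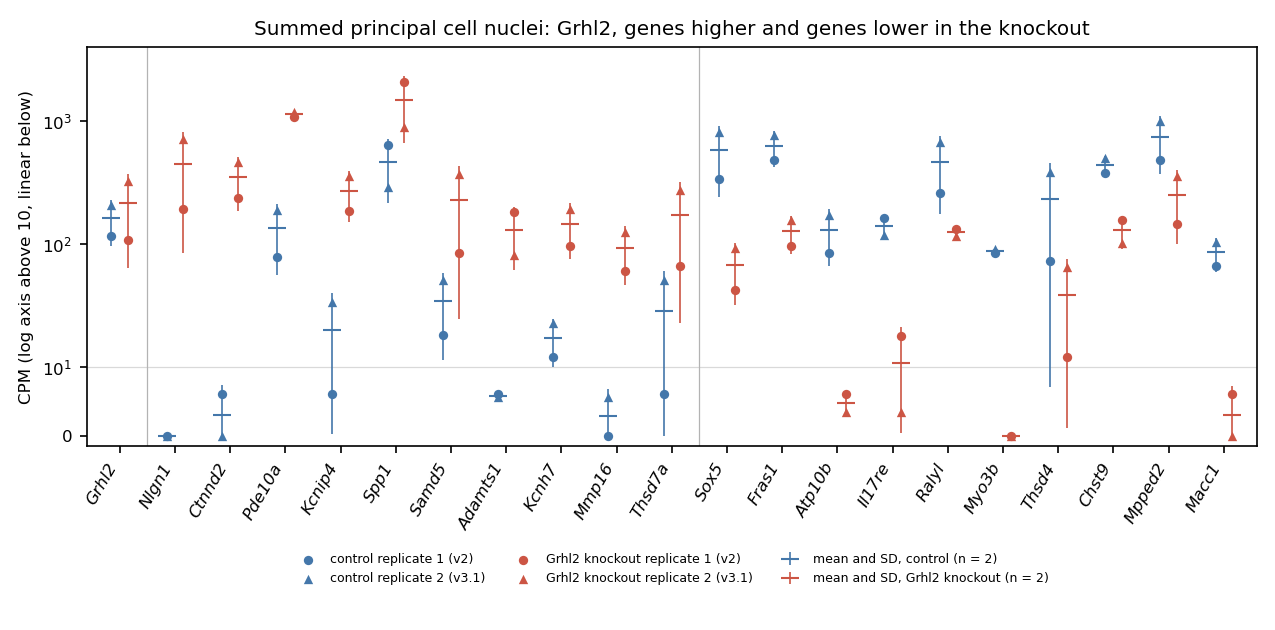
CPM of Grhl2 and of the genes named in principal cells, per library (points), with the mean and SD of each group (n = 2); the axis is logarithmic above 10 CPM and linear below. Each named gene other than Grhl2 moves one way in both kits, as the rule that picked it required, while Grhl2 does not.

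In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a term for the kit called 202 of 5842 genes, 119 higher and 83 lower. DESeq2 called 10, all of them among the 202, and 803 genes had an unadjusted p under 0.05 in edgeR. Without the kit term, edgeR called 0 genes (104 at an unadjusted p under 0.05). Leaving out control replicate 1, knockout replicate 1, control replicate 2 or knockout replicate 2, with no kit term, left 18, 14, 0 and 4 genes (111 at an unadjusted p under 0.05 where 0 were called). The count was 40 at Leiden resolution 0.5, 70 at a UMI minimum of 500, 28 and 26 once free RNA was subtracted, 4 and 7 with equal numbers of nuclei, and 550 with the inner medullary clusters included.

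Of the 30 fixed gene lists, tubule injury genes rose in principal cells. 3 of 6 measured members were higher among all genes and 6 when adjusted over the list alone, with none lower (camera adjusted p = 5.85e-11, adjusted p = 0.873 with an estimated correlation). Besides Spp1 these were Tnfrsf12a, the receptor for TWEAK (2.72 ± 0.50), and Clu, the secreted chaperone clusterin (1.60 ± 0.31). Lcn2, an iron-carrier protein released by injured tubules, had a log2 change of 1.59 ± 0.53 and missed the threshold (edgeR adjusted p = 0.0682). Genes of the medullary collecting duct rose as a list, with 4 of 10 higher and 1 lower both among all genes and when adjusted over the list alone (camera adjusted p = 0.0288, adjusted p = 0.873 with an estimated correlation). The keratins Krt19 (2.34 ± 0.62) and Krt7 (0.84 ± 0.26) and the calcium-binding protein S100a6 (1.47 ± 0.33, abundant in free RNA) were among those higher. Aqp4, a basolateral water channel, was lower (-0.93 ± 0.29), but with the control nuclei split into 3 parts the knockout lay below 1 part (-2.06) and above the others (1.46 and 1.05). None of 11 genes of the cortical collecting duct passed over all genes and 1 was lower when adjusted over the list alone (camera adjusted p = 0.973). These 2 lists set the border between principal cells and the inner medullary clusters, so neither is an independent result. With the inner medullary clusters described next counted as principal cells, Spp1 was at -0.32 and S100a6 at -0.53. Over all other settings Krt19 spanned 0.13 to 2.93, while with 1 library left out its lowest value was 1.82, so its size depends on the processing.

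The unfolded protein response list rose (1 of 12 higher, 3 when adjusted over the list alone, camera adjusted p = 0.0174, adjusted p = 0.873 with an estimated correlation), with Hspa5, a chaperone of the endoplasmic reticulum, at 1.10 ± 0.25. The epithelial junction and barrier list, which holds genes of the kind GRHL2 controls, did not pass as a list (camera adjusted p = 0.832). 2 of its 18 measured members were higher, among them Cldn7, a tight junction claudin (1.48 ± 0.37), and when adjusted over the list alone 4 were higher and 3 lower. Epcam, an epithelial adhesion molecule, had a log2 change of 0.74 ± 0.26 (edgeR adjusted p = 0.0902) and Esrp1, an epithelial splicing regulator, of -1.16 ± 0.44 (edgeR adjusted p = 0.134). None of 10 osmotic stress genes passed over all genes and 1 was lower when adjusted over the list alone (camera adjusted p = 0.797), with Nfat5, the transcription factor of the hyperosmotic response, at -0.47 ± 0.21. In the vasopressin and water transport list 1 of 10 members, Aqp4, was lower over all genes and also over the list alone (camera adjusted p = 0.141). Ptger1, a prostaglandin E2 receptor, was lower (-1.24 ± 0.35), though not against every part of the control nuclei (-1.94, -1.06 and 0.12). Transcripts of the proximal tubule, as markers of another cell type in these nuclei, went both ways, with Gpx3 higher (0.63 ± 0.16, abundant in free RNA, -0.91 without knockout replicate 1 and -0.04 without control replicate 2) and Slc7a13 lower (-1.03 ± 0.28). Subtraction of free RNA left less than 50% of the UMIs of Spp1, S100a6, Hspa5, Gpx3 and Slc7a13 in principal cells, and Slc7a13 could then not be tested.

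The next comparison concerned the deepest part of the collecting duct. 2 clusters, each with 6 raised principal cell markers, carried more of the medullary than of the cortical collecting duct list, and are called the inner medullary clusters. The first held 461, 79, 240 and 10 nuclei (control replicate 1, knockout replicate 1, control replicate 2, knockout replicate 2), and the second held 0, 15, 0 and 87. Knockout replicate 2 thus lay mostly in the second cluster and the other 3 libraries mostly in the first. The second had 0 principal cell markers among its 10 leading genes and more of another class, so the rule used for all other classes would have left it without a name. It held 87 of the 97 nuclei of knockout replicate 2, and without it that library has too few nuclei for a test, so the comparison rests on it. The genes that define the clusters are not given as results. Pde10a was higher by a log2 of 5.32 ± 0.56 (SE, n = 2 per group) and Nav2 by 2.84 ± 0.36. Kcnc2, a potassium channel, had 3 UMIs in the control and 128 in the knockout libraries (ratio 173, 57.9 to 850) and Adgra1 had 3 and 36 (ratio 48.7, 15.4 to 247). Ptges, a prostaglandin E synthase, fell (-3.15 ± 0.59), as did Hnrnpr, an RNA-binding protein (-2.11 ± 0.34). Tm6sf1 had 204 UMIs in the control and 1 in the knockout libraries (0.0199, 0.000501 to 0.112), Myo3b had 195 and 2 (0.0416, 0.00500 to 0.152) and Ism2 had 131 and 1 (0.0310, 0.000778 to 0.176). The edgeR adjusted p-values of these genes lay between 3.68e-05 (Pde10a) and 0.00499 (Ptges). Nav2 was at 0.64 without knockout replicate 2.

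Osmotic stress genes fell in the inner medullary clusters. Without the genes that lead or define the clusters, 3 of 12 measured members were lower and none higher (camera adjusted p = 0.000554, adjusted p = 0.872 with an estimated correlation). Examples were Hspb1, a small heat shock protein (-1.76 ± 0.39), and Sgk1, a kinase that regulates sodium transport (-1.21 ± 0.30). edgeR called 138 of 6109 genes, 107 higher and 31 lower, and DESeq2 called 44, all among the 138. With each library left out in turn, in the order above, the counts were 12, 99, 10 and 10. When clustering was repeated without the genes called in the collecting duct, the 4 libraries shared 1 inner medullary cluster, which met the naming rule for principal cells, and 45 genes were called, of which 42 were among the 138. The count was 21 at Leiden resolution 1.5, 272 at a second resolution of 0.3, 61 and 0 with equal numbers of nuclei, and 112 and 0 once free RNA was subtracted with the first and the second profile (462 at an unadjusted p under 0.05 with the second).

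The other distal segments shared part of these changes. In intercalated cells, which secrete acid or base, edgeR called 68 of 7609 genes (40 higher, 28 lower) and DESeq2 called 1. Kcnd2, a potassium channel, rose by a log2 of 2.95 ± 0.33 (SE, n = 2 per group here and in the segments that follow), Nlgn1 by 2.00 ± 0.31, Slc13a1, a sodium-sulfate cotransporter, by 1.73 ± 0.26 and Cyp4a10, a fatty acid omega-hydroxylase, by 2.72 ± 0.39. Cadps had 2 UMIs in the control and 55 in the knockout libraries (ratio 23.4, 6.18 to 198). Hs3st5, a heparan sulfate sulfotransferase, changed by -2.43 ± 0.30, Syt7 by -1.99 ± 0.30, Kcnq3 by -1.69 ± 0.27 and Sgcd by -1.39 ± 0.20, and Bglap3 had 61 and 2 UMIs (0.0279, 0.00331 to 0.105). Slc26a4, which encodes the chloride-bicarbonate exchanger pendrin, fell by 0.73 on the log2 scale, with SE 0.16 (edgeR adjusted p = 0.00147). It was the only member of the acid-base transport list past the threshold over all genes (1 of 17 lower, 3 when adjusted over the list alone, camera adjusted p = 0.0289, adjusted p = 0.873 with an estimated correlation). The class pools a cluster led by Slc26a4 (246, 257, 181 and 181 nuclei, in the order above) and a cluster led by Kit (45, 105, 93 and 190). The cluster led by Kit made up more of the class in the knockout of both kits. A change of mix within the class was not tested. The fall of Slc26a4 and the result for the list are therefore not assigned to changes within nuclei. Leaving out each library in turn left 2, 0, 1 and 3 genes (87 at an unadjusted p under 0.05 without knockout replicate 1), and Kcnq3 was at 0.16 without control replicate 2. Hs3st5 was at -0.31 and Sgcd at -0.55 without control replicate 2, and Cyp4a10 at 0.16 without knockout replicate 1. Less than 50% of the UMIs of Slc13a1 and Cyp4a10 was left after subtraction of free RNA, and Cyp4a10 could then not be tested, so these rises are not assigned to intercalated cells.

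In the connecting tubule edgeR called 50 of 8017 genes (40 higher, 10 lower) and DESeq2 called 1. The metallothioneins Mt1 (1.47 ± 0.21, abundant in free RNA) and Mt2 (1.68 ± 0.27), Cyp4a10 (1.89 ± 0.31), Kcnc2 (1.39 ± 0.21), Spp1 (1.16 ± 0.20, abundant in free RNA) and Clu (1.01 ± 0.20) rose, and Samd5 had 1 and 58 UMIs (ratio 48, 8.28 to 1930). Slc7a13 (-1.28 ± 0.26), Npnt, a matrix ligand of integrins (-0.95 ± 0.21), Plekha1 (-0.85 ± 0.20), Dnase1 (-1.15 ± 0.22) and Cryab, a small heat shock protein abundant in free RNA (-0.79 ± 0.19), fell. Leaving out each library in turn left 2, 2, 0 and 5 genes (91 at an unadjusted p under 0.05 without control replicate 2), and the other scaling of libraries called 20. Mt1 was at 0.18, Mt2 at -0.17 and Cyp4a10 at -0.82 without knockout replicate 1, Dnase1 at 0.85 and Cryab at -0.05 without control replicate 1, and Npnt at 0.26 and Plekha1 at 0.03 without control replicate 2. In the pair left whole, Cyp4a10 was at 0.86 (v3.1) and Npnt at -0.31 (v2), and the other 5 of these genes kept more than 50% of their change. Less than 50% of the UMIs of Mt1, Mt2, Cyp4a10, Slc7a13, Dnase1 and Cryab was left after subtraction of free RNA. Slc7a13 and Dnase1 could then not be tested and Cyp4a10 was at 0.28 with the second profile, so these 3 are not assigned to the connecting tubule. Mt1 is not assigned to it either, as it rose alike in the free RNA itself (1.25 in the v2 and 1.27 in the v3.1 pair, first profile).

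In the thick ascending limb, which reabsorbs salt without water, edgeR called 51 of 10537 genes (28 higher, 23 lower) and DESeq2 called 11. Pde10a rose by a log2 of 3.08 ± 0.22, Tnfrsf12a by 2.14 ± 0.36, Slc13a1 by 1.34 ± 0.18, Spp1 by 1.03 ± 0.14 (abundant in free RNA), Cyp4a14 by 4.57 ± 0.37 and Apoc3, an apolipoprotein, by 2.71 ± 0.35. Myo3b (-1.48 ± 0.18), Tenm2 (-1.11 ± 0.15), Rgs6, a regulator of G-protein signalling (-0.88 ± 0.14), Mef2c, a transcription factor (-1.97 ± 0.31), and Kirrel3 (-1.59 ± 0.26) fell. Leaving out each library in turn left 0, 0, 0 and 7 genes (72 to 197 at an unadjusted p under 0.05 where 0 were called). Without knockout replicate 1 Apoc3 was at -0.36 and Spp1 at 0.51, and without control replicate 2 Kirrel3 was at 0.06, Tenm2 at -0.19 and Rgs6 at -0.43. Apoc3 was at 1.10 in the v3.1 pair. Less than 50% of the UMIs of Tnfrsf12a, Slc13a1, Spp1, Cyp4a14 and Apoc3 was left after subtraction of free RNA. Cyp4a14 and Apoc3 could then not be tested and Slc13a1 only with the second profile (3.47, SE 1.30), so these 3 are not assigned to the thick ascending limb.

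In the distal convoluted tubule edgeR called 10 of 10470 genes (8 higher, 2 lower) and DESeq2 called 4. Cyp4a14 (5.03 ± 0.35), Apoc3 (3.32 ± 0.34), Gsta2, a glutathione transferase (1.45 ± 0.20), and Mt1 (1.28 ± 0.15, abundant in free RNA) rose, as did Gm21154, with 3 and 64 UMIs (ratio 18.7, 6.10 to 92.8). Adamtsl3 (-1.69 ± 0.20) and Dnase1 (-1.31 ± 0.19) fell. Adamtsl3 was a leading gene of one of the clusters pooled in this class (39, 30, 605 and 705 nuclei, in the order above). A change of mix within the class was not tested, so the fall of Adamtsl3 is not assigned to changes within nuclei. The list of distal sodium, calcium and magnesium transport genes fell (camera adjusted p = 1.89e-07, adjusted p = 0.873 with an estimated correlation), with 0 of 13 members past the threshold over all genes and 4 lower when adjusted over the list alone. The count was 59 with the other scaling of libraries, and leaving out each library in turn left 0, 0, 0 and 6 genes (66 to 153 at an unadjusted p under 0.05 where 0 were called). Apoc3, Mt1 and Gsta2 were at -0.09, -0.10 and -0.02 without knockout replicate 1, Dnase1 at 0.53 without control replicate 1 and Adamtsl3 at 0.26 without control replicate 2. Apoc3 was at 1.52 in the v3.1 pair. Less than 50% of the UMIs of Cyp4a14, Apoc3, Gsta2, Mt1 and Dnase1 was left after subtraction of free RNA. Cyp4a14, Apoc3 and Gsta2 could then not be tested and Dnase1 only with the second profile (-2.46, SE 1.34), so these 4 are not assigned to the distal convoluted tubule. Mt1 was at 1.41 and 1.10 after subtraction. It rose alike in the free RNA itself (1.25 in the v2 and 1.27 in the v3.1 pair, first profile). Free RNA left behind would keep that change, so Mt1 is not assigned to this class either.

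In the thin limb, which runs through the medulla, the osmotic stress list fell. 2 of its 12 measured members were lower over all genes and 7 when adjusted over the list alone (camera adjusted p = 2.75e-06, adjusted p = 0.873 with an estimated correlation). Akr1b3, the aldose reductase that makes the osmolyte sorbitol, fell by 1.30 on the log2 scale (SE 0.24). Hnrnpr (-1.64 ± 0.25), Ranbp3l (-1.24 ± 0.28), Rassf6 (-1.46 ± 0.31), Camk2b (-1.62 ± 0.34) and Ndrg4 (-2.27 ± 0.50) were lower as well. Slc13a1 (2.23 ± 0.36), Adamts1 (2.94 ± 0.49), Hmga2, a chromatin protein (2.49 ± 0.46), Itgb6, an integrin subunit (1.65 ± 0.32), Igfbp2 (2.60 ± 0.54) and Spp1 (0.98 ± 0.23, abundant in free RNA) rose. edgeR called 20 of 4925 genes, 10 in each direction, and DESeq2 called 0 (52 at an unadjusted p under 0.05 in DESeq2). With each library left out in turn the counts were 0, 0, 0 and 2 (47 to 134 at an unadjusted p under 0.05 where 0 were called), and Camk2b was at 0.24 without control replicate 2. Spp1 was at 0.42 without control replicate 2, Ranbp3l at -0.40 without control replicate 1, and Itgb6 at 0.65 and Igfbp2 at 1.16 without knockout replicate 2. Slc13a1 was at 0.97 and Igfbp2 at 0.52 in the v2 pair, and Ranbp3l was at -0.52 in the v3.1 pair. Slc13a1 also rose in the free RNA itself (0.89 in the v2 and 1.22 in the v3.1 pair, first profile), so its rise is not assigned to the thin limb. Of the genes named here, only Spp1 had less than 50% of its UMIs left after subtraction of free RNA.

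The proximal tubule, endothelial nuclei, podocytes and immune nuclei served as classes in which Hoxb7-Cre is not known to act. In the proximal tubule edgeR called 18 of 13991 genes (8 higher, 10 lower) and DESeq2 called 30. Cyp4a10 rose by a log2 of 1.84 ± 0.15, Kynu by 1.54 ± 0.16, Hp, which encodes haptoglobin, by 2.05 ± 0.22 and Igfbp1 by 2.03 ± 0.24. The fatty acid oxidation list rose (1 of 18 members over all genes, 8 when adjusted over the list alone, camera adjusted p = 3.7e-08, adjusted p = 0.873 with an estimated correlation). The tubule injury list also rose (1 of 16, 10 when adjusted over the list alone, camera adjusted p = 3.64e-11, adjusted p = 0.873 with an estimated correlation), with Fga, a fibrinogen chain, at 1.73 ± 0.23. Naaladl2 (-1.57 ± 0.16), Col19a1 (-1.56 ± 0.18), Ncam2 (-1.34 ± 0.16), Cntnap5a (-1.38 ± 0.17) and AC163354.1 (-1.30 ± 0.16) fell. The class pools several clusters of uneven size. Kynu was a leading gene of one (1530, 1567, 24 and 177 nuclei, in the order above) and Cntnap5a of another (9, 34, 2051 and 2315). A change of mix within the class was not tested, so the changes of Kynu and Cntnap5a are not assigned to changes within nuclei. Leaving out each library in turn left 6, 0, 0 and 49 genes (97 to 189 at an unadjusted p under 0.05 where 0 were called), the other scaling called 2, and Cntnap5a was at 1.47 without control replicate 2. Without knockout replicate 1 Hp was at 0.075, Kynu at 0.65 and Cyp4a10 at 0.84, and without control replicate 2 Naaladl2 was at -0.58 and Col19a1 at -0.53. Less than 50% of the UMIs of Cyp4a10 and Hp was left after subtraction of free RNA, and Hp could then not be tested.

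In endothelial nuclei edgeR called 14 of 8230 genes (9 higher, 5 lower) and DESeq2 called 1. Mt1 (1.61 ± 0.24, abundant in free RNA), Slc13a1 (1.35 ± 0.24), Cyp4a10 (1.80 ± 0.32), Apoc3 (2.38 ± 0.43) and Gsta2 (1.41 ± 0.29) rose, and Slco4a1 (-2.28 ± 0.41), Dnase1 (-1.21 ± 0.24), Pax2, a transcription factor of kidney epithelia (-2.03 ± 0.40), Cryab (-1.02 ± 0.22, abundant in free RNA) and Akr1b3 (-1.12 ± 0.25) fell. Most of these genes are known from tubule cells. Free RNA made up an estimated 76.9%, 78.8%, 46.3% and 49.6% of the UMIs in endothelial nuclei, and 8 of the 14 genes had too few UMIs left to test once it was subtracted, with either profile. Less than 50% of the UMIs was left for Mt1, Slc13a1, Cyp4a10, Apoc3, Gsta2, Dnase1, Cryab and Akr1b3, and these changes are not assigned to endothelial cells. Of Slco4a1, 70.1% and 90.8% of the UMIs were left (first and second profile), and of Pax2 40.7% and 77.8%. In podocytes edgeR called 3 of 3253 genes, all higher, and DESeq2 called 0 (22 at an unadjusted p under 0.05 in DESeq2). They were Ctgf, a matrix-associated growth factor target (2.03 ± 0.39), Mt2 (2.15 ± 0.42) and Cebpd, a transcription factor of the acute phase response with 1 and 80 UMIs (ratio 67.6, 11.8 to 2700). In immune nuclei edgeR called 0 of 613 genes (20 at an unadjusted p under 0.05) and DESeq2 called 0. Leaving out each library in turn left 8, 0, 0 and 2 genes in endothelial nuclei and 0, 0, 0 and 2 in podocytes (26 to 131 at an unadjusted p under 0.05 where 0 were called). Without knockout replicate 1, Cyp4a10, Apoc3, Mt1 and Gsta2 were at -0.05, -0.62, 0.09 and 0.64 in endothelial nuclei, and Mt2 was at 0.55 in podocytes. In endothelial nuclei Dnase1 was at 0.25 without control replicate 1 and Akr1b3 at -0.41 without knockout replicate 2.

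**Figure D2:**
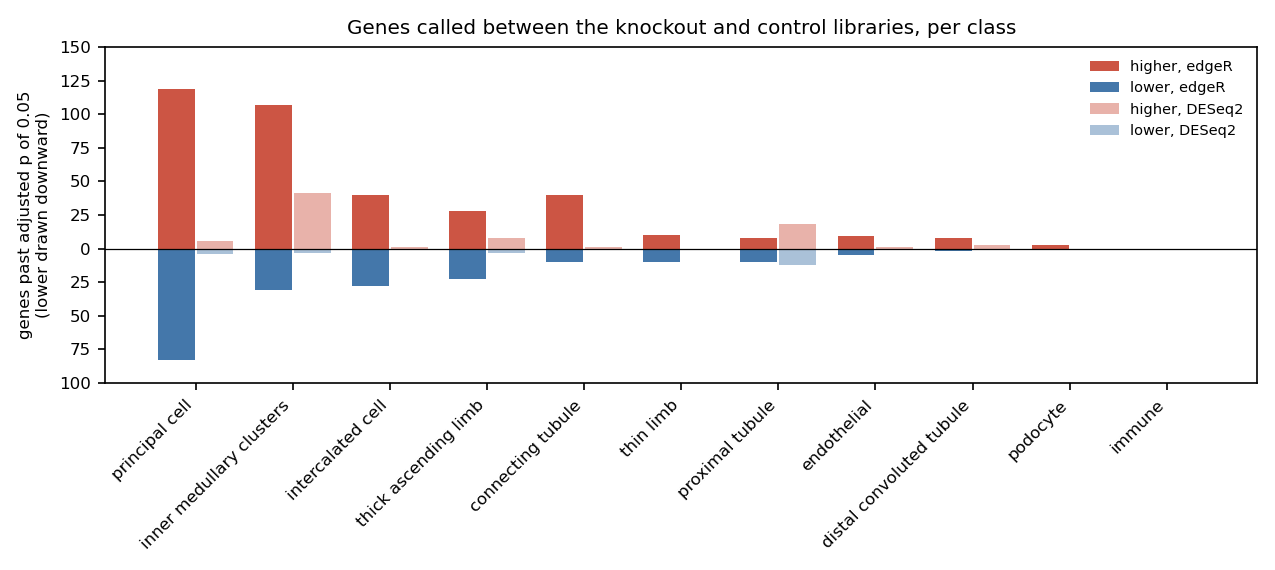
Number of genes called per class between the knockout and control libraries (adjusted p under 0.05), higher drawn upward and lower downward, by edgeR (solid) and DESeq2 (pale). Principal cells have the most calls by edgeR, 119 higher and 83 lower, and the proximal tubule has 18 by edgeR and 30 by DESeq2.

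Over the other settings of edgeR the number of calls spanned 0 to 72 in intercalated cells, 0 to 75 in the connecting tubule, 0 to 103 in the distal convoluted tubule, 0 to 200 in the thick ascending limb and 0 to 45 in the thin limb. It spanned 0 to 275 in the proximal tubule, 0 to 42 in endothelial nuclei and 0 to 10 in podocytes, and over all classes but immune nuclei 10 to 462 genes had an unadjusted p under 0.05 where 0 were called.

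Transcripts encoded by mitochondria fell as a list in every class tested. The median log2 change of the list was -0.51 in principal cells, -0.64 in the thick ascending limb, -0.84 in the thin limb and -0.68 in the proximal tubule (camera adjusted p = 4.94e-08, 2.00e-19, 1.47e-15 and 2.94e-11, each with an adjusted p = 0.873 with an estimated correlation). In principal cells 2 of 12 members were lower over all genes, among them mt-Nd4 (-0.65 ± 0.18) and mt-Atp6 (-0.59 ± 0.17), both abundant in free RNA, and 9 when adjusted over the list alone. The empty droplets showed the same direction, with 4.41% and 2.36% mitochondrial UMIs in the v2 pair (control, knockout) and 6.26% and 4.33% in the v3.1 pair. After subtraction of free RNA at most 22.8% of the UMIs of mt-Atp6 was left in the thick ascending limb and thin limb. For mt-Nd4 in the connecting tubule and thick ascending limb it was at most 30.2%. The falls of both genes are not assigned to the nuclei of these classes. Over all classes camera called 59 of 266 pairs of list and class, including the medullary and cortical collecting duct lists in the inner medullary clusters that these lists define, and none was called with an estimated correlation, where the lowest adjusted p was 0.873.

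A test of the difference asked whether the genotype effect in principal cells differs from that in the thick ascending limb, a tubule segment outside the collecting duct. edgeR called 69 of 5728 genes, 29 with a more positive and 40 with a more negative effect in principal cells. Of the 172 genes called in principal cells that could be tested, 48 differed. The effect on Ctnnd2, Kcnip4, Kcnh7, Chst11, a chondroitin sulfotransferase, and Plcl1 was more positive in principal cells. The log2 differences were 7.55, 3.89, 3.75, 3.43 and 1.43 (SE 0.94, 0.52, 0.65, 0.60 and 0.18). In the thick ascending limb these genes were at 0.16, -0.345, -0.655, -0.51 and -0.366, none past the threshold. Sox5, Chst9, Thsd4, Il17re and Pde4d, a cyclic AMP phosphodiesterase, differed the other way, by -2.76, -2.24, -2.53, -3.66 and -1.07 (SE 0.28, 0.26, 0.36, 0.58 and 0.18). Their edgeR adjusted p-values lay between 2.02e-18 and 5.16e-06. Without the block for each library, with the kit terms kept, 32 genes were called. With each library left out in turn, the differences spanned 5.15 to 11.26 for Ctnnd2, 3.70 to 5.35 for Kcnip4, 3.07 to 3.90 for Kcnh7, 3.05 to 8.36 for Chst11 and 0.16 to 2.36 for Plcl1. They spanned -2.94 to -2.68 for Sox5, -2.96 to -1.20 for Chst9, -2.86 to -1.93 for Thsd4, -4.67 to -3.05 for Il17re and -1.45 to -0.62 for Pde4d.

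The last comparison concerned the share of nuclei in each class. Inner medullary clusters made up 5.22% of nuclei in control replicate 1 (exact 95% interval 4.76 to 5.70), 0.922% in knockout replicate 1 (0.745 to 1.13), 2.71% in control replicate 2 (2.38 to 3.07) and 0.881% in knockout replicate 2 (0.715 to 1.07). The knockout over control ratio was 0.177 in the v2 pair and 0.325 in the v3.1 pair. It was 0.201 and 0.349 when clustering left out the genes called in the collecting duct. The class depends on the second clustering. Without it, 2, 3, 191 and 91 nuclei were named so, with ratios of 1.3 and 0.383, while urothelium held 616, 225, 114 and 93. At a second resolution of 0.8 the ratios were 0.181 and 0.534. Principal cells changed less, with 3.12% and 2.53% in the control and 2.49% and 2.11% in the knockout libraries, ratios of 0.797 and 0.832. Endothelial nuclei made up 3.04% and 4.50% in the control and 6.89% and 5.56% in the knockout libraries. The proximal tubule held 52.2 ± 5.39% and 50.6 ± 9.16% (SD, n = 2), a difference of -1.60 percentage points that was 4.16 at a UMI minimum of 1000. With 2 libraries against 2 the two-sided exact permutation test cannot give a p below 0.333, the value found for the inner medullary, principal cell and endothelial shares, so no share passed a test.

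**Figure D3:**
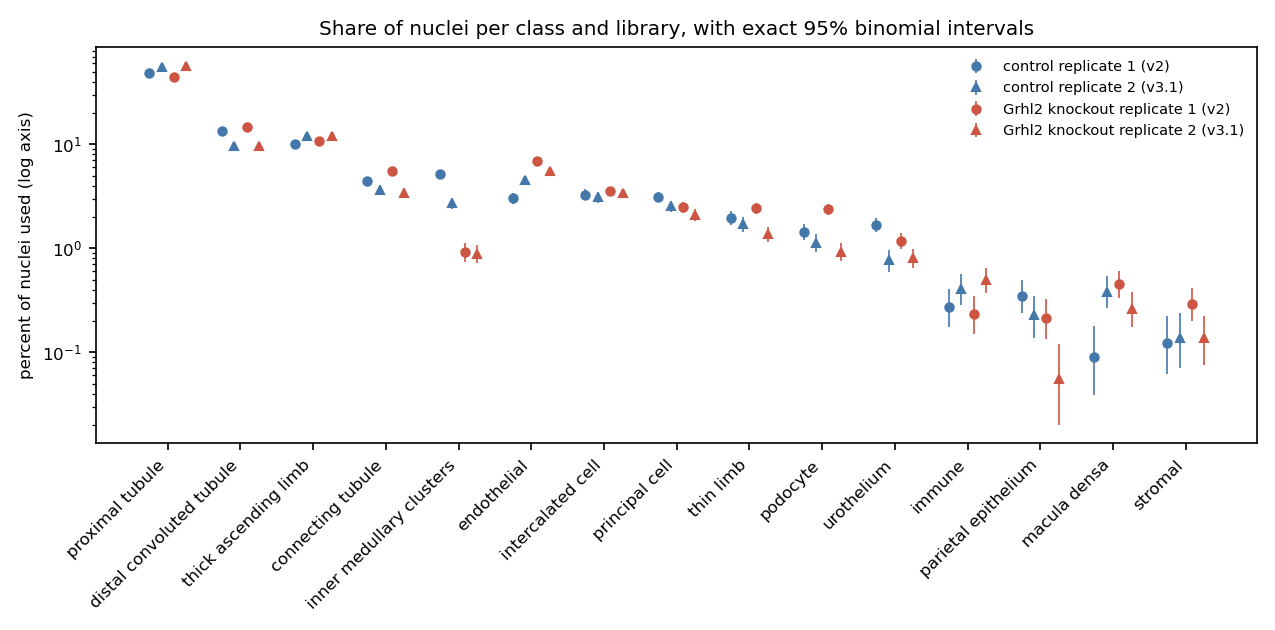
Share of the nuclei used in each class and library in percent, on a log axis, with exact binomial 95% intervals; blue marks control, red knockout, circles v2 and triangles v3.1. The inner medullary clusters lie at 5.22% and 2.71% in the control and at 0.922% and 0.881% in the knockout libraries.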

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

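All tests of explanations here were chosen after the result was seen, other than the test of variants linked to the targeted locus, which was written before.

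The genotype effect differed between principal cells and the thick ascending limb for 69 genes. The 5 genes with the smallest p in each direction, taken by rule, were Ctnnd2 (7.55), Kcnip4 (3.89), Kcnh7 (3.75), Chst11 (3.43) and Plcl1 (1.43) in one direction, and in the other Il17re (-3.66), Sox5 (-2.76), Thsd4 (-2.53), Chst9 (-2.24) and Pde4d (-1.07).

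A different mix of principal cell types was weighed as an explanation of the changes in principal cells. With the control nuclei split into 3 parts, 119 of 119 higher genes lay above every part. Of the lower genes, 76 of 83 lay below every part. With 4 parts these were 117 of 119 and 71 of 83. The genes were called against these same nuclei, which favours such a result. The parts hold only nuclei classed as principal cells, so a mix with inner medullary or urothelium nuclei was not weighed. With 4 parts, 45 of the 119 higher and 19 of the 83 lower genes lay more than a log2 of 1 beyond every part. A mix of these parts alone gives no level beyond all of them, so it is an unlikely source of those changes. For calls closer to a part the counts cannot decide, as the choice of genes favours them. With 3 parts, the 7 lower genes not below every part were Aqp4, Ptger1, Dnm3, Papss1, Rgl3, Sfxn5 and Tbck, and for these a mix stays open. 1 mix of the parts came within a log2 of 0.5 for 5 of these but for no more. With 4 parts a mix stays open for more genes, higher ones among them. Free RNA was the next candidate. Subtraction with the second profile left 184 of the 202 called genes to test, and with the first 166. With genes no longer tested set at 0, the median signed log2 change was 1.44 and 1.496, against 1.31 before. Subtraction from low counts can itself enlarge a log2 change, so this median cannot decide alone. Less than 50% of the UMIs was left with both profiles for 31 of the 202 genes. Free RNA alone is thus an unlikely source of most of the changes. Still, only 26 and 28 genes were called after subtraction, 23 and 22 of them among the 202, while the median SE of the genes still tested went from 0.33 to 0.44 and from 0.32 to 0.55. Variants linked to the targeted locus would gather on chromosome 15, which held 3.47% of the called and 4.16% of the tested genes (95% interval 1.40 to 7.01, Fisher's exact p = 0.857). The called genes on it were 7. Positions within the chromosome were not used, and the 7 genes were not looked at one by one. A share over the chromosome is no test of a single gene. Linked variants therefore stay open for each of the 7, and genes named above may be among them.

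The lower share of inner medullary nuclei may come from less inner medulla in the knockout slices. The knockout over control ratio of the thin limb share was 1.25 in the v2 pair and 0.798 in the v3.1 pair, and that of urothelium was 0.704 and 1.04. None was under 0.5, as this explanation would give, but not all were over 1, so it was left open. A move of nuclei to neighbouring clusters is less likely, as the 4 classes together had ratios of 0.587 and 0.667. Assignment moved by the changed genes themselves is also less likely, since the ratio was at most 0.349 when clustering left these genes out. Without the second clustering the ratio was 1.3 in the v2 pair, where only 2 and 3 nuclei were named so.

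Of the 22 genes called in 2 or more classes outside the collecting duct, the proximal tubule not counted, 7 could reflect free RNA, as in each class that called them less than 50% of their UMIs and no testable or half-size change were left after subtraction. These were Apoc3, Cyp4a10, Cyp4a14, Gldc, Gsta2, Tmem252 and Tmem37. 3 genes kept more than 50% of their UMIs and most of the change in each class, Pde10a, Myof and Slco4a1, which free RNA is unlikely to produce. The other 12 met neither rule.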

How the results depend on the processing

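Named genes kept direction and call in 1528 of 1925 other settings, were weaker in 386, stronger in 3 and reversed in 8; with DESeq2 75 of 116 were weaker, and with 1 library left out 439 of 552 were weaker and 20 reversed. Of 137 values of single genes past the threshold, 19 reversed and 27 fell under 50% of their size with some library left out. Leaving out a library also drops the kit term. Of 45 of these values with a whole pair left, 6 were under 50% in that pair and 0 reversed, though most were chosen for the same sign in both pairs. Values that kept 50% or more with each library left out were not counted, though some were also under 50% in the pair left whole. Other causes were not tested, but equal numbers use fewer nuclei and subtraction leaves fewer genes tested. Not run, as a library had under 20 nuclei, were UMI minimum 1000 in principal cells, connecting tubule, podocytes and immune nuclei, the inner medullary clusters without second clustering, and stromal nuclei. Not run, as no cluster took the name, were the thin limb at UMI minimums 500 and 1000, resolution 0.5 and second resolutions 0.2 and 0.3, and the inner medullary clusters at 0.05, where the urothelium held more nuclei. Immune nuclei were left out by design at equal numbers without immune.

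Genes called are given in the order principal, intercalated, connecting tubule, distal convoluted, thick limb, thin limb, proximal tubule, endothelial, podocyte, inner medullary, where they moved by more than 1.5-fold. DESeq2 gave 10, 1, 1, 4, 11, 0, 30, 1, 0 and 44. RLE gave connecting tubule 20, distal convoluted 59, thin limb 34, proximal 2, endothelial 27, podocyte 10. No count filter gave distal convoluted 100, thick limb 139, thin limb 40, proximal 275, endothelial 26, podocyte 7, inner medullary 262. UMI minimum 500 gave principal 70, connecting tubule 14, distal convoluted 103, endothelial 30, podocyte 5, and 1000 gave intercalated 9, thick limb 30, proximal 6, endothelial 0. Doublets kept gave connecting tubule 7, distal convoluted 97, thick limb 200, thin limb 45, proximal 1, endothelial 42, podocyte 6, inner medullary 253. Resolution 0.5 gave principal 40, distal convoluted 77, thick limb 25, proximal 1, endothelial 36, and 1.5 gave distal convoluted 63, proximal 2, endothelial 30, inner medullary 21. Free RNA subtracted gave principal 28, intercalated 0, connecting tubule 0, distal convoluted 0, thick limb 0, thin limb 10, proximal 0, endothelial 4, and the second profile 26, 0, 0, 0, 1, 0, 0, 0, 0 and 0. Equal numbers gave 4, 3, 2, 0, 0, 0, 0, 0, 0 and 0, and without immune 7, 12, 12, 1, 3, 12, 3, 2, 0 and 61. Second resolution 0.8 gave thin limb 0 and inner medullary 257, 0.3 inner medullary 272, clustering without called genes inner medullary 45, and inner medullary included principal 550. With 1 library left out the counts spanned 0 to 18, 0 to 3, 0 to 5, 0 to 6, 0 to 7, 0 to 2, 0 to 49, 0 to 8, 0 to 2 and 10 to 99. Where edgeR gave 0, 15 to 462 genes had an unadjusted p under 0.05, and 22 to 52 for DESeq2.

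Without the kit term as the block, which pairs the libraries, 0 genes were called in all 10 classes (10 to 229 at an unadjusted p under 0.05). 38 lists were then called. The interaction without its block for each library kept the kit terms and called 32 genes. In these fits 127 of 141 named gene values, those of the interaction among them, were weaker. Lists called fell from 59 to 0 with an estimated correlation (0 unadjusted), 0 by fry (31 unadjusted) and 0 by mixed fry (37 unadjusted), and were 46 to 86 with 1 library left out. The interaction then spanned 3 to 23 genes.

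Grhl2 was at 0.83 with inner medullary included, and from -0.65 to 0.98 with 1 library left out. With inner medullary included Spp1 was at -0.32, S100a6 -0.53, Epcam -0.32 and Nfat5 0.15, and at second resolution 0.05 Aqp4 0.24 and Nfat5 0.32. Spp1 in thin limb was at -0.48 at 0.8, and endothelial Gsta2 at -0.03 with equal numbers without immune. Some principal cell genes kept their sign but shrank in some setting, among them Krt19 to 0.13, Hspa5 to 0.27 and Ralyl to -0.43. With 1 library left out, ranges that crossed 0 were Gpx3 in principal cells -0.91 to 2.14; Kcnq3 in intercalated cells -4.38 to 0.16; in connecting tubule Mt2 -0.17 to 3.87, Cyp4a10 -0.82 to 3.94, Dnase1 -3.58 to 0.85, Npnt -1.66 to 0.26, Plekha1 -1.86 to 0.03; in distal convoluted tubule Apoc3 -0.085 to 5.40, Mt1 -0.10 to 2.63, Gsta2 -0.02 to 3.02, Adamtsl3 -3.33 to 0.26, Dnase1 -3.50 to 0.53; in thick limb Apoc3 -0.36 to 4.83, Kirrel3 -3.37 to 0.055; Camk2b in thin limb -3.81 to 0.24; Cntnap5a in proximal tubule -4.31 to 1.47; in endothelial nuclei Cyp4a10 -0.05 to 3.21, Apoc3 -0.62 to 4.92, Dnase1 -3.03 to 0.25.

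Differences in share (percentage points) at UMI minimum 1000 were endothelial 0.433, immune -0.181, intercalated -0.120, principal -0.116, urothelium -0.822. In the same setting the proximal tubule was at 4.16 (-1.60 before), the thick limb at -0.482 (0.305 before) and the distal convoluted tubule at -0.073 (0.620 before), within 1 SD of the first value but with the other sign. In all, 23 of 224 differences in share changed sign, in 10 of 15 classes, none of them in principal cells, endothelial nuclei or inner medullary clusters. Without second clustering inner medullary was at -0.663 and urothelium at -2.61, and at 0.05 principal was at -0.054 and urothelium at -3.77. With 1 library left out inner medullary spanned -4.32 to -1.81. Nuclei called at a mitochondrial limit of 1% were 156, 2597, 3067 and 7636, and at UMI minimum 1000 control replicate 1 had 1631 and knockout replicate 1 3187.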

Other observations

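Tubule injury genes rose as a list by camera in most classes beyond principal cells and the proximal tubule. The thick ascending limb had adjusted p = 1.83e-07 (2 of 7 members higher over all genes, 5 when adjusted over the list alone), the connecting tubule 3.7e-08 (2 of 5, 3 alone), intercalated cells 0.00662 (1 of 6, 2 alone) and the thin limb 0.00828 (1 of 6, 2 alone). In the distal convoluted tubule it was 0.00828 (0 of 8, 2 alone), in podocytes 2.21e-05 (0 of 6, 3 alone) and in endothelial nuclei, with their high share of free RNA, 0.0305 (0 of 10, 1 alone). Each had adjusted p = 0.873 with an estimated correlation. In the inner medullary clusters the list did not pass (camera adjusted p = 0.663, 1 of 6 higher over all genes and over the list alone, adjusted p = 0.913 with an estimated correlation). Osmotic stress genes fell by camera in the connecting tubule (adjusted p = 0.000204, 1 of 11 lower) and in the proximal tubule (adjusted p = 0.000878, 0 of 13 over all genes and 4 lower when adjusted over the list alone), with adjusted p = 0.873 with an estimated correlation in both.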
